A study of Homo sapiens with 14 samples.

How the data were processed

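RNA from C4-2B cells was measured on 14 Affymetrix expression arrays. Per the labels' protocols, the cells were grown in medium with 5% serum and transfected 24 h after plating. The control siRNA was non-specific and used at 5 nM, and the SGTA siRNA was a pool of 3 siRNAs at 1.67 nM each. Hormone-stripped serum was added 4 h after transfection. At 72 h the cells received 1 nM hormone or ethanol vehicle, and the sample labels give 16 h of treatment. RNA was extracted on columns, and biotinylated RNA was prepared from 300 ng. The labels name the hormone of the treated samples as DHT. They number the replicates but do not say whether these came from separate cultures or days, so p-values measure the spread between these samples, which may be technical.

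The deposited values are log2 probe set signals, 1 column per array, for 33297 probe sets. Per the submitters' processing notes, RMA and limma were used; their versions and settings are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes into a log2 value. Such values compress the changes of dim genes. Column medians ran from 6.333 to 6.433. No scanner files or detection calls were used here, so the number of arrays and the signal over background limit precision, and no depth applies.

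Gene names came from the platform annotation. It gave 1 symbol for 19460 probe sets and several symbols for 1754 probe sets, and 12083 probe sets were unlisted. Symbols were updated through gene identifiers for 19429 probe sets, and 31 kept the annotated symbol. Probe sets with several symbols or none entered no gene result. The brightest probe set was kept for each gene, which left 18417 genes, of which 769 had several probe sets. No filter on dim genes was applied. Coordinates are not printed, because the build of the annotation is not given in the sources used here.

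The model was limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups over all 14 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment over 18417 genes for each comparison. It had 10 residual degrees of freedom and a prior of 4.85. Genes with an adjusted p under 0.05 are called changed, and errors beside log2 changes are standard errors from this model. The comparisons were SGTA siRNA against control siRNA in vehicle and in DHT, DHT against vehicle with each siRNA, and the difference between the DHT responses.

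The 28 gene lists were fixed from general knowledge before the data were examined, as were the comparisons, the rule for named genes and most alternatives. Of their 912 genes, 835 were measured. Lists were tested with camera at a preset correlation of 0.01 and adjusted over 28 lists. The same test with an estimated correlation and the fry test were alternatives. For the 10 vehicle arrays, list means were also compared with exact two-sided permutation tests over 252 arrangements, with 0.00794 as the smallest p. A comparison of 2 against 2 arrays cannot reach p under 0.05 in an exact test.

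The rule named SGTA and its paralog SGTB. It took the 10 largest rises and falls past the threshold without overlap between groups for knockdown in vehicle and for DHT with control siRNA. It took 5 of each for knockdown in DHT and for DHT with SGTA siRNA, and the 5 smallest p-values for the difference between DHT responses. Up to 4 members of each list, and 8 fixed genes, completed it. Of those 8, 4 had a probe set with 1 symbol and are reported.

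The fits were tested on simulated data with the spread of each gene and known changes over 18417 genes. For knockdown in vehicle, 23.9% of changes of 0.25 on the log2 scale, 92.1% of changes of 0.5 and 99.4% of changes of 1 were called, and 5.06% of calls were false. For knockdown in DHT, 43.7% of changes of 0.5 were called. For the difference between DHT responses, 19.7% of changes of 0.5 and 91.7% of changes of 1 were called. In the simulated vehicle comparison, 10 of 10 lists shifted by 0.15 were called and 0 of 10 unshifted lists were. These simulations had genes that varied independently, so they do not test how often correlated lists are called by chance.

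The alternatives changed 1 choice at a time: the replicate number as a block, only the arrays compared, an intensity trend with a robust prior, array weights, only genes above the median of all probe sets (6.387), the mean of all probe sets of a gene, every probe set as its own feature, quantile normalization again, centring on column medians, stricter thresholds and leaving out each array. Alternatives added after the data were seen were a crossed pairing of the DHT arrays, leaving out a pair of SGTA siRNA vehicle arrays and leaving out small nucleolar RNA genes. For comparisons that share control arrays, the covariance that sharing gives was simulated 50 times with no effects, and the control arrays were split in 20 ways.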

Results

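Gene expression was measured in C4-2B cells, an androgen-independent human prostate cancer line derived from LNCaP, after siRNA against SGTA or a non-specific control siRNA, with DHT or vehicle. DHT, dihydrotestosterone, is a natural ligand of the androgen receptor. SGTA encodes a co-chaperone that binds heat shock proteins and takes part in the handling of tail-anchored and mislocalised membrane proteins. There were 5 arrays with control siRNA and 5 with SGTA siRNA in vehicle, and 2 with each siRNA in DHT. The number of arrays limits precision, most of all in DHT. Correlations across probe sets ran from 0.990 to 0.997 among the 10 vehicle arrays, from 0.995 to 0.997 among the 4 DHT arrays and from 0.964 to 0.974 between vehicle and DHT arrays. The labels give no batch, and each treatment could lie in a batch of its own, in which case batch and treatment cannot be told apart.

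The knockdown was first checked on the targeted gene. SGTA had a log2 signal of 9.91 ± 0.12 (SD, n = 5) with control siRNA and 7.99 ± 0.08 (SD, n = 5) with SGTA siRNA in vehicle. Its change was -1.92 ± 0.07 (SE), a 3.79-fold lower signal (limma adjusted p = 4.14e-10), and SGTA ranked first by p in this comparison. In DHT the change was -2.24 ± 0.11, 4.74-fold lower (limma adjusted p = 3.38e-08, 2 arrays each). Every array with SGTA siRNA lay below every array with control siRNA. The paralog SGTB was also lower in vehicle, by -0.63 ± 0.08 (limma adjusted p = 8.95e-05), while in DHT its change of -0.15 ± 0.12 did not pass (limma adjusted p = 0.851); the difference between these changes did not pass either (0.49 ± 0.15, limma adjusted p = 0.452).

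**Figure D1:**
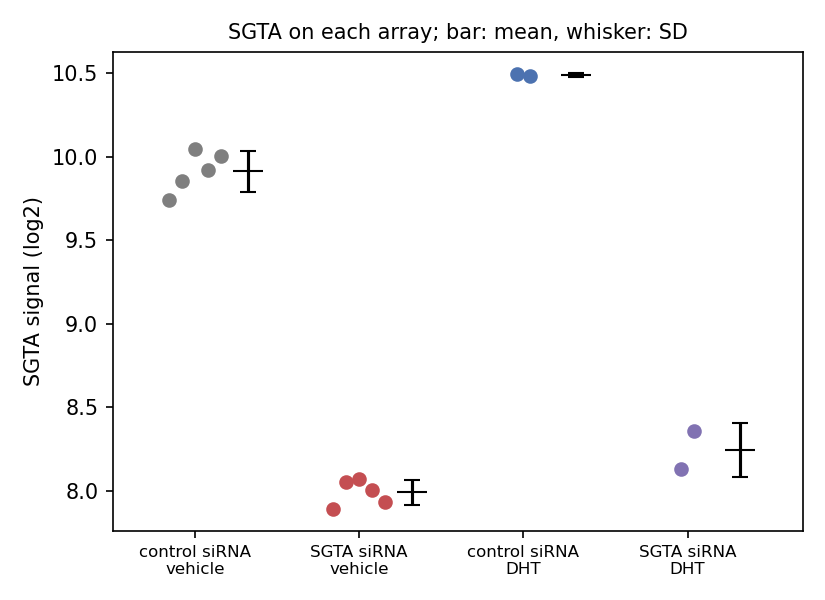
SGTA signal (log2, y axis) on each of the 14 arrays, by siRNA and treatment (x axis). Points are arrays, the bar is the group mean and the whisker the SD; all SGTA siRNA arrays lie below all control siRNA arrays.

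The comparison of SGTA siRNA with control siRNA in vehicle asked which genes change when SGTA is lowered without hormone. The largest falls after correction were in KCNJ13, a potassium channel gene (-2.08 ± 0.14), S100A10, which encodes the annexin A2 partner p11 (-1.96 ± 0.10), CFAP69 (-1.54 ± 0.10), the death ligand gene TNFSF10 (-1.49 ± 0.18), MAB21L3 (-1.30 ± 0.11), the myosin kinase gene MYLK (-1.25 ± 0.06), the phospholipase gene PLA2G2A (-1.25 ± 0.10), ACTRT3 (-1.19 ± 0.09) and NAPEPLD (-1.17 ± 0.07). The largest rises were in CYP1A2, a drug-metabolising cytochrome (1.16 ± 0.13), IGFBP3, which binds insulin-like growth factors (0.99 ± 0.08), GPX8 (0.97 ± 0.13), PLD1 (0.94 ± 0.10), BCAT1, a branched-chain amino acid transaminase (0.93 ± 0.07), LRRC31 (0.93 ± 0.12), CD24 (0.82 ± 0.18), the cyclin gene CCND3 (0.75 ± 0.08), TOMM20 (0.72 ± 0.12) and CHAC1 (0.71 ± 0.07). In all, 1949 of 18417 genes changed, 759 higher and 1190 lower, by limma with adjustment over all genes. Most changes were small: 138 were at least 1.5-fold and 17 at least 2-fold. With columns centred on their medians, 479 genes were higher and 1421 lower, so the share of rises moved from 38.9% to 25.2%. Without SGTA siRNA vehicle replicates 1 and 3, which lay apart from their group on the second principal component, 1236 genes were called; that pair was chosen after the data were seen.

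Genes of DNA replication, ribosome biogenesis, amino acid synthesis and transport, and tRNA synthetases were higher with SGTA siRNA in vehicle. Of 51 measured G1/S and replication genes, 11 rose and none fell, with a median of 0.15 (camera adjusted p = 7.99e-09); adjusted over the list alone, 21 rose. They included the phosphatase gene CDC25A (0.41 ± 0.07), ORC6 (0.30 ± 0.08) and the helicase subunit MCM4 (0.26 ± 0.07). This list gave an adjusted p = 0.0741 with an estimated correlation. Of 32 ribosome biogenesis genes, 10 rose and none fell, with a median of 0.14 (camera adjusted p = 3.17e-07), led by GRWD1 (0.39 ± 0.05) and IPO4 (0.33 ± 0.05); adjusted over the list alone, 15 rose. Its adjusted p was 0.0189 with an estimated correlation, and it was the 1 list of this comparison that kept its call there. Of 23 amino acid synthesis and transport genes, 11 rose (camera adjusted p = 8.91e-07; adjusted p = 0.0719 with an estimated correlation), among them the cystine transporter SLC7A11 (0.60 ± 0.07), asparagine synthetase ASNS (0.60 ± 0.07) and the glutamine transporter SLC1A5 (0.42 ± 0.05). Of 19 tRNA synthetase genes, 8 rose (camera adjusted p = 1.79e-05; adjusted p = 0.0908 with an estimated correlation), led by GARS1 (0.49 ± 0.06). Of 61 G2/M genes, 7 rose (camera adjusted p = 0.0318; adjusted p = 0.599 with an estimated correlation), and the exact permutation p of the list mean was 0.175. MKI67, a proliferation marker, changed by -0.13 ± 0.06 and did not pass (limma adjusted p = 0.213). The calls of ORC6 (0.28 without SGTA siRNA vehicle replicate 5), MCM4 (0.25 without SGTA siRNA vehicle replicate 5) and the G2/M list (mean of 0.04 without SGTA siRNA vehicle replicate 5) were lost there.

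Genes of glycolysis and lipid synthesis were lower. Of 35 hypoxia and glycolysis genes, 14 fell and none rose, with a median of -0.19 (camera adjusted p = 1.51e-10); adjusted over the list alone, 19 fell. They included the fructose bisphosphate regulators PFKFB3 (-0.88 ± 0.15) and PFKFB4 (-0.57 ± 0.12), the collagen hydroxylase P4HA1 (-0.76 ± 0.09) and NDRG1 (-0.62 ± 0.11). This list gave an adjusted p = 0.167 with an estimated correlation. Of 26 fatty acid synthesis genes, 8 fell (camera adjusted p = 4.81e-06; adjusted p = 0.0719 with an estimated correlation), including the desaturases SCD (-0.34 ± 0.06) and FADS2 (-0.22 ± 0.04). Of 19 cholesterol synthesis genes, 6 fell (camera adjusted p = 5.05e-05; adjusted p = 0.0719 with an estimated correlation), led by the sterol carrier gene STARD4 (-0.97 ± 0.07). Exact permutation of the array means gave p = 0.00794, the smallest possible, for each of these 3 lists and for the G1/S, ribosome biogenesis, amino acid and tRNA synthetase lists, or 0.0185 adjusted over 28 lists.

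**Figure D2:**
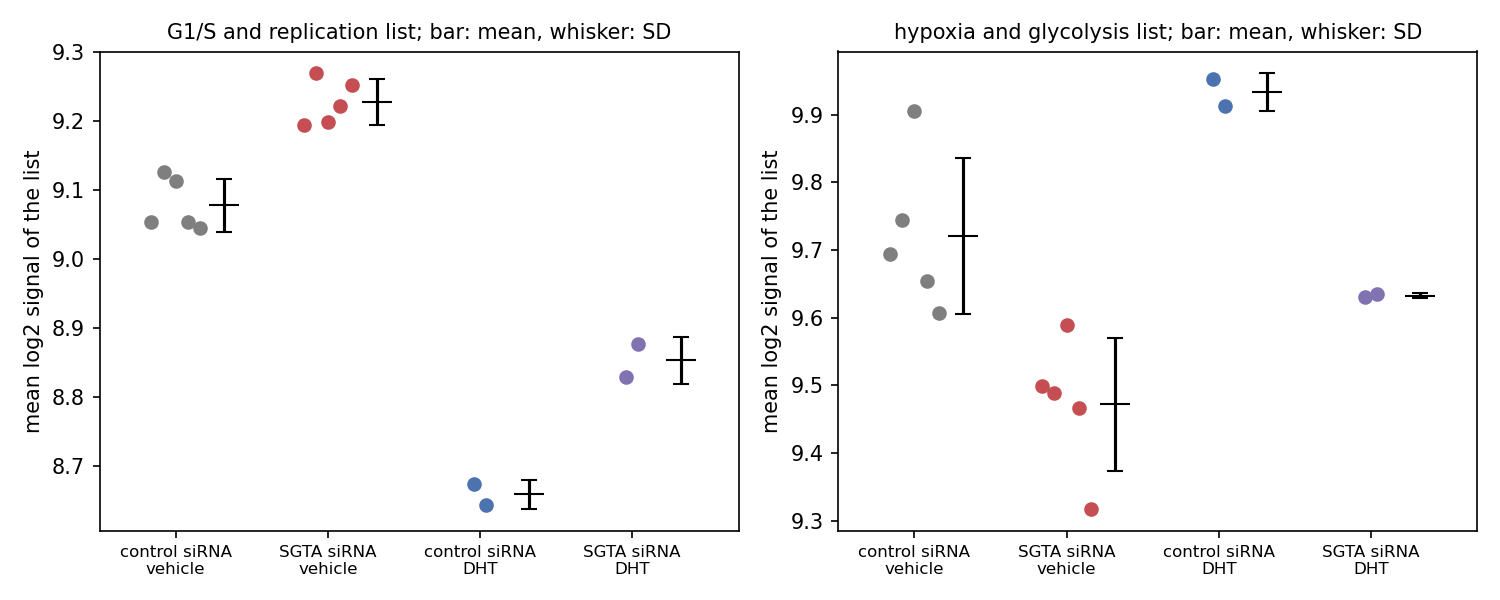
Mean log2 signal (y axis) of the G1/S and replication list and of the hypoxia and glycolysis list on each array, by siRNA and treatment (x axis). Points are arrays, bars group means and whiskers SDs; G1/S means were 9.08 with control and 9.23 with SGTA siRNA in vehicle, and hypoxia and glycolysis means were 9.72 and 9.47.

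Prostate and signalling genes were also lower in vehicle. Of 18 luminal prostate genes, 4 fell (camera adjusted p = 5.05e-05; adjusted p = 0.0965 with an estimated correlation): STEAP1 (-1.10 ± 0.07), ACP3, prostatic acid phosphatase (-0.68 ± 0.09), STEAP2 (-0.62 ± 0.05) and the ion channel gene TRPM8 (-0.58 ± 0.09). Of 65 androgen-induced genes, 16 fell and 3 rose, with a median of -0.05 (camera adjusted p = 0.0076; adjusted p = 0.117 with an estimated correlation); SNAI2 was a member that rose (0.61 ± 0.09). KLK3, which encodes prostate-specific antigen, changed by -0.11 ± 0.07 and did not pass (limma adjusted p = 0.368). Of 28 p53 target genes, 6 fell and 1 rose (camera adjusted p = 0.0033; adjusted p = 0.0965 with an estimated correlation), including TP53INP1 (-0.65 ± 0.06) and MDM2 (-0.55 ± 0.06). Of 42 PI3K, AKT and mTOR pathway genes, 8 fell and 2 rose (camera adjusted p = 0.0446; adjusted p = 0.244 with an estimated correlation), including PIK3R1 (-0.65 ± 0.07), PIK3CB (-0.49 ± 0.06) and PIK3CD (-0.49 ± 0.06). Of 30 FOXO target genes, 6 fell (camera adjusted p = 0.0398; adjusted p = 0.167 with an estimated correlation), while SESN3 rose (0.57 ± 0.05). Of 30 adhesion and mesenchymal genes, 5 fell and 1 rose (camera adjusted p = 0.0318; adjusted p = 0.0858 with an estimated correlation), led by the integrin gene ITGAV (-0.74 ± 0.06). Of 38 oxidative phosphorylation genes, 2 fell (camera adjusted p = 0.0408; adjusted p = 0.517 with an estimated correlation; exact permutation p = 0.27). The FOXO, PI3K, adhesion and oxidative phosphorylation lists lost their calls without control siRNA vehicle replicate 3, with means of -0.06, -0.05, -0.06 and -0.03.

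The remaining 13 of 28 lists were not called in vehicle. Among 41 unfolded protein response genes 8 rose and 3 fell (camera adjusted p = 0.306), with CHAC1 (0.71 ± 0.07) and EDEM1 (-0.50 ± 0.05) at the ends; the median was -0.01 and the mean 0.06. Exact permutation and fry called the list (adjusted p = 0.0318 and 0.00462), and camera did not with an estimated correlation (adjusted p = 0.544). Among 23 tail-anchored protein pathway genes, SGTA and SGTB included, 1 rose and 3 fell (camera adjusted p = 0.306), with a median of 0.01 and a mean of -0.10. Exact permutation and fry called it too (adjusted p = 0.0185 and 0.00204), with the siRNA target among its members, and camera did not with an estimated correlation (adjusted p = 0.588). Camera adjusted p was 0.206 for 43 chaperone genes, 0.542 for 33 proteasome genes, 0.161 for 41 autophagy and lysosome genes, 0.206 for 33 androgen-repressed genes and 0.236 for 27 NF-kB genes. It was 0.895 for 38 interferon-stimulated genes, whose list mean varied between arrays of a group, from 6.38 to 7.65 with control siRNA and from 6.51 to 7.73 with SGTA siRNA. Markers of other cell types gave 0.895 for basal epithelium, 0.498 for neuroendocrine cells, 0.938 for fibroblasts, 0.514 for endothelium and 0.306 for leukocytes.

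**Figure D3:**
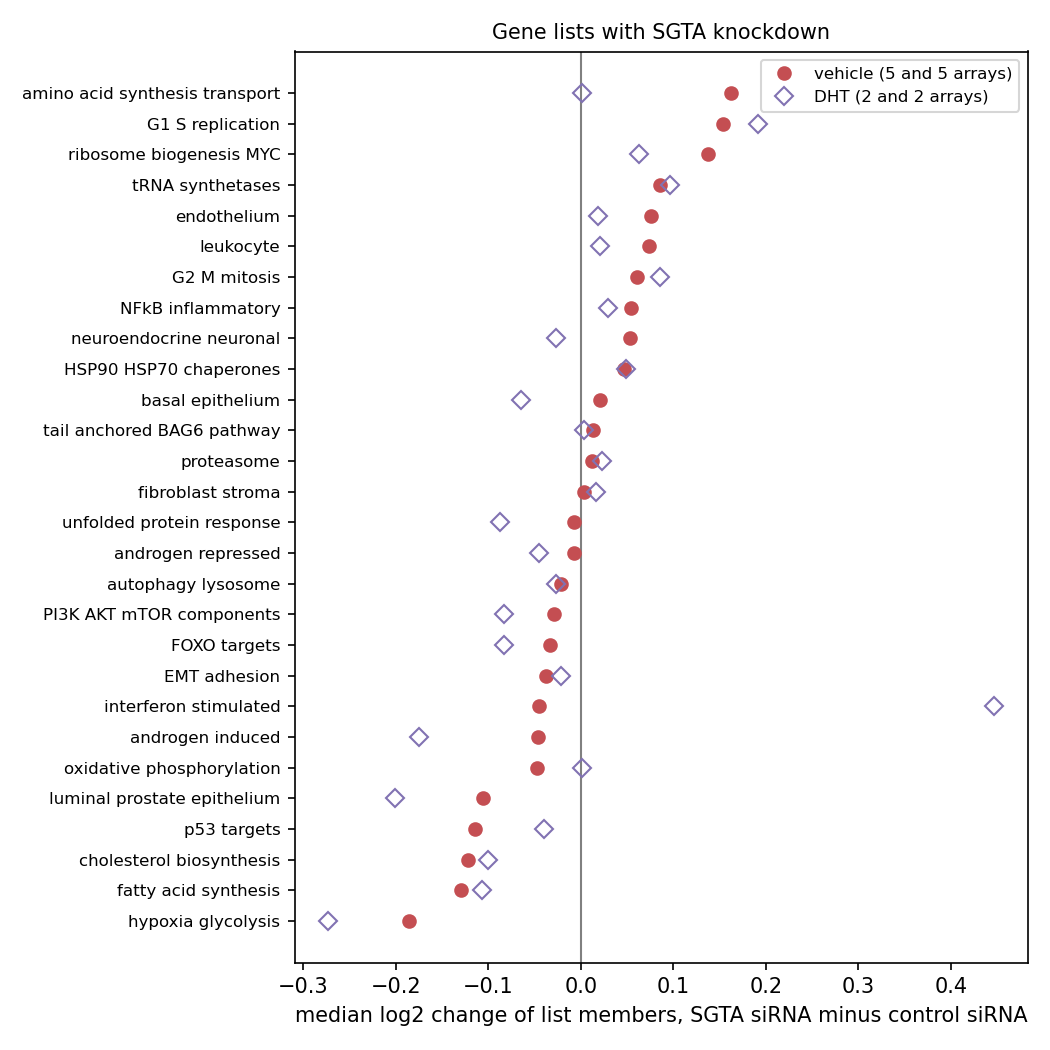
Median log2 change of the members of each of the 28 gene lists (y axis) with SGTA siRNA against control siRNA (x axis, log2). Filled circles are vehicle arrays (5 and 5) and open diamonds DHT arrays (2 and 2); the hypoxia and glycolysis list had medians of -0.19 and -0.27, and the G1/S list 0.15 and 0.19.

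The same knockdown was examined in DHT with 2 arrays per siRNA. S100A10 (-1.80 ± 0.16), MAB21L3 (-1.40 ± 0.17), PLA2G2A (-1.27 ± 0.16) and TRPM8 (-1.0 ± 0.14) fell, as did TARP (-1.75 ± 0.33) and the acute phase gene ORM1 (-1.33 ± 0.29). The glucuronosyltransferase gene UGT2B28 (1.5 ± 0.19), GLYATL2 (1.29 ± 0.14), SNORD115-32 (1.26 ± 0.22), SNORD115-25 (1.13 ± 0.26), GPX8 (1.08 ± 0.21) and the actin gene ACTA2 (1.00 ± 0.13) rose. SNORD115-25 had DHT means of 3.38 with control siRNA and 4.51 with SGTA siRNA. SNORD115-32 had 4.32 and 5.58, and UGT2B28 had 4.24 and 5.75. All these means lay under the median of all probe sets (6.387), and signal from related gene copies was not tested. In all, 270 genes changed, 88 higher and 182 lower, by limma with adjustment over all genes. The count was 60 without control siRNA DHT replicate 1, 84 without control siRNA DHT replicate 2, 79 without SGTA siRNA DHT replicate 1 and 74 without SGTA siRNA DHT replicate 2. It was 152 with the replicate number as a block and 666 with array weights. TARP (-1.65), ORM1 (-1.54), GPX8 (1.02), SNORD115-32 (1.24) and SNORD115-25 (1.10) lost their calls without control siRNA DHT replicate 2, and SNORD115-25 had a change of 0.66 and lost its call without SGTA siRNA DHT replicate 2.

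Of 65 androgen-induced genes, 8 fell and none rose with SGTA siRNA in DHT, with a median of -0.18 (camera adjusted p = 2.07e-14; adjusted p = 0.00279 with an estimated correlation). Of 51 G1/S genes, 3 rose, MCM4 (0.50 ± 0.11), DTL (0.41 ± 0.09) and RFC3 (0.32 ± 0.07), with a list median of 0.19 (camera adjusted p = 2.42e-14; adjusted p = 0.046 with an estimated correlation). These were the 2 lists whose calls held with an estimated correlation, of 13 called. Ribosome biogenesis, the list that held in vehicle, had DHT means of 9.757 with control siRNA and 9.81 with SGTA siRNA. In vehicle they were 9.82 and 9.959. Amino acid list means were 9.736 and 9.769 in DHT, against 9.77 and 9.955 in vehicle. No ribosome biogenesis or tRNA synthetase gene was called in DHT, and ASNS (0.50 ± 0.10) was the called amino acid gene. Of 35 hypoxia and glycolysis genes, 2 fell, ENO2 (-0.82 ± 0.14) and ALDOC (-0.55 ± 0.12), with a list median of -0.27 (camera adjusted p = 3.47e-15; adjusted p = 0.14 with an estimated correlation). The luminal prostate (camera adjusted p = 3.2e-07), fatty acid (3.53e-05) and cholesterol (0.000116) lists were also lower, with adjusted p = 0.0654, 0.0896 and 0.0654 with an estimated correlation. Interferon-stimulated genes had a median of 0.45 with 0 of 38 members called (camera adjusted p = 0.000933; adjusted p = 0.67 with an estimated correlation), and their mean change was -0.21 without SGTA siRNA DHT replicate 2 and 0.06 without control siRNA DHT replicate 2. MCM4 (0.46), DTL (0.37), RFC3 (0.38), ENO2 (-0.74) and ALDOC (-0.52) lost their calls without control siRNA DHT replicate 1.

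Knockdown changes in vehicle and in DHT share no arrays. Their log2 changes correlated across genes (r = 0.457, rho = 0.348; genes are not independent replicates). Of 1949 genes called in vehicle, 1667 (85.5%) had the same sign in DHT. The 197 genes called in both comparisons all had the same sign. Independent lists would share 28.6, but this is no chance value for the overlap. Both comparisons took the spread of each gene from the same model, so a gene with a small spread is more likely to be called in both.

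The comparison of DHT with vehicle asked how these cells respond to androgen with each siRNA. With control siRNA, 61 of 65 androgen-induced genes rose and none fell, with a median of 1.40 (camera adjusted p = 4.29e-33; adjusted p = 6.74e-05 with an estimated correlation). The largest rises included the metalloreductase gene STEAP4 (5.41 ± 0.09), the transcription factor gene SNAI2 (4.81 ± 0.12), PGC (3.80 ± 0.13), RHOU (3.45 ± 0.09), the kinase gene SGK1 (3.32 ± 0.08), CHRNA2 (3.20 ± 0.11) and TARP (3.02 ± 0.28), and the small nucleolar RNAs SNORD41 (4.04 ± 0.23), SNORA23 (3.86 ± 0.17) and SNORA71D (3.79 ± 0.14). The largest falls were in the mTOR inhibitor gene DEPTOR (-3.12 ± 0.07), MTND2P28 (-3.00 ± 0.14), SYTL2 (-2.89 ± 0.11), KCNJ13 (-2.87 ± 0.18) and SCARNA17 (-2.77 ± 0.11). SESN3 (-2.63 ± 0.07), INSIG2 (-2.62 ± 0.12), LMO4 (-2.49 ± 0.10), PLD1 (-2.32 ± 0.13) and NAP1L2 (-2.31 ± 0.13) followed. Signal from related gene copies was not tested for MTND2P28. KLK3 rose by 1.27 ± 0.09, IGF1R by 1.48 ± 0.16 and the cell cycle inhibitor gene CDKN1A by 0.57 ± 0.08, while MKI67 changed by -0.05 ± 0.08 (limma adjusted p = 0.666). SGTA itself rose by 0.58 ± 0.09 (limma adjusted p = 6.76e-05).

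Replication genes were lower in DHT with control siRNA: 34 of 51 G1/S genes fell and 5 rose (camera adjusted p = 6.58e-07; adjusted p = 0.263 with an estimated correlation), with MCM6 (-1.44 ± 0.09) and MCM2 (-1.22 ± 0.08) among the falls and GINS2 (1.29 ± 0.08) among the rises. Of 61 G2/M genes, 33 fell and 12 rose (camera adjusted p = 0.00176; adjusted p = 0.925 with an estimated correlation). Of 18 luminal prostate genes, 11 rose and 4 fell (camera adjusted p = 0.00176; adjusted p = 0.382 with an estimated correlation), with SLC45A3 (2.53 ± 0.12) and SPDEF (2.43 ± 0.08) higher and ACP3 (-1.90 ± 0.11) lower. Of 41 unfolded protein response genes, 23 rose and 9 fell (camera adjusted p = 0.0122; adjusted p = 0.263 with an estimated correlation), led by DNAJB9 (1.79 ± 0.10). Of 19 tRNA synthetase genes, 11 fell and 5 rose (camera adjusted p = 0.0237; adjusted p = 0.75 with an estimated correlation). The androgen-repressed list was not called in this comparison.

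By limma with adjustment over all genes, DHT changed 8204 genes with control siRNA, 4021 higher and 4183 lower, and 1041 of them at least 2-fold. With SGTA siRNA it changed 7682 genes, 3668 higher and 4014 lower. The responses correlated across genes (r = 0.937), and 8082 of 8204 genes (98.5%) had the same sign. With SGTA siRNA, 60 of 65 androgen-induced genes rose, with a median of 1.08 (camera adjusted p = 1.66e-31; adjusted p = 8.44e-05 with an estimated correlation), and STEAP4 rose by 5.28 ± 0.09, SNAI2 by 4.66 ± 0.12 and KLK3 by 1.16 ± 0.09. Genes for olfactory receptors, which are mostly silent outside the nose, were called in 10.6% of 341 cases by DHT with control siRNA and in 1.17% by knockdown in vehicle. Over all genes the shares were 44.55% and 10.58%. The adjusted threshold lets larger p-values pass where more genes are called, so the receptor rates are not on an equal footing.

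Whether the knockdown altered the response to DHT was tested as the difference between the responses. The androgen-induced genes rose on average by 1.56 ± 0.02 (SE) with control siRNA and by 1.39 ± 0.02 with SGTA siRNA, and 51 of 65 members had the smaller response with SGTA siRNA. The difference was -0.18 ± 0.03 (camera adjusted p = 6.13e-06; adjusted p = 0.0539 with an estimated correlation). Exact permutation of the list means decides nothing here. Its p of 0.333 is the smallest open to it, because the 4 DHT arrays have 3 distinct splits and the knockdown difference of list means had the same sign in vehicle (-0.08) and in DHT (-0.26). No member passed on its own over all genes, and 4 were lower adjusted over the list alone. The mean response of the list with SGTA siRNA was 88.8% of that with control siRNA. This percentage leans on a few dim members. The differences were largest for TARP (-1.84), ORM2 (-1.23) and ORM1 (-1.10), and the next was IGF1R (-0.55). With control siRNA in vehicle, the means of TARP, ORM2 and ORM1 lay under the median of all probe sets (6.387). The median difference of the list, which such members move less, was -0.15. The percentage without these genes was not computed. Over the 8204 genes called by DHT with control siRNA, the slope of the responses was 0.913. Choosing genes by their control response can lower this slope, but a smaller response may not be particular to the list.

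**Figure D4:**
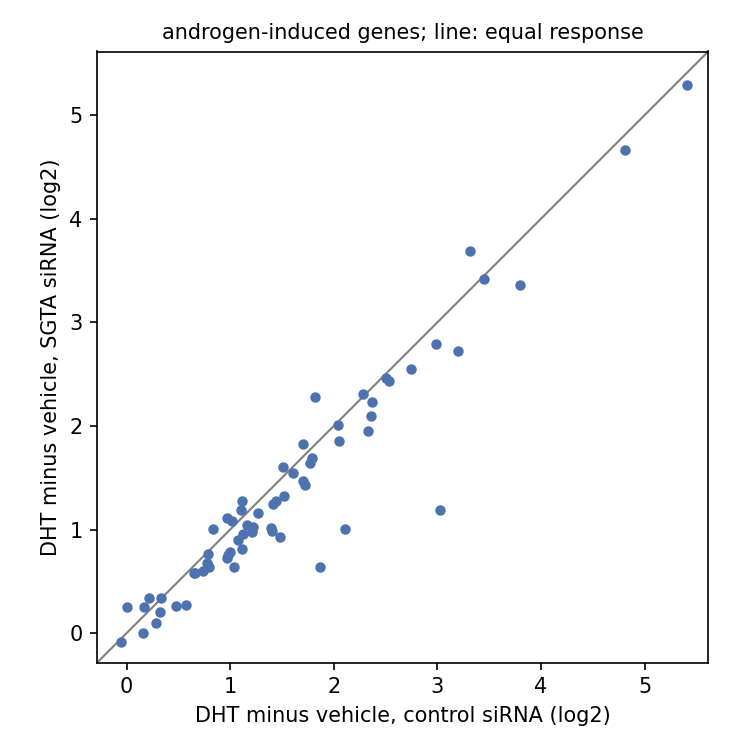
Response to DHT of each of the 65 androgen-induced genes (DHT minus vehicle, log2) with control siRNA (x axis) and with SGTA siRNA (y axis). Points are genes and the line marks equal responses; 51 of 65 genes lie below the line.

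Of all genes, 15 had a DHT response that differed with knockdown (9 more positive, 6 more negative; 1234 at an unadjusted p under 0.05). CYP2U1 (-1.08 ± 0.09, limma adjusted p = 0.000173) and LRRK1 (-0.80 ± 0.12) rose with DHT under both siRNAs, but less with SGTA siRNA. The CYP2U1 mean went from 7.52 to 9.15 with control siRNA and from 7.46 to 8.01 with SGTA siRNA. STEAP1 (1.05 ± 0.13) rose more with SGTA siRNA, and ACTRT3 (1.24 ± 0.16) and MYNN (0.76 ± 0.11) fell less. Their means were lower with SGTA siRNA in vehicle and close between siRNAs in DHT. In DHT they were 10.99 and 10.94 for STEAP1, 5.70 and 5.75 for ACTRT3 and 7.99 with each siRNA for MYNN. The count fell to 1 without control siRNA DHT replicate 2, 5 without control siRNA DHT replicate 1, 3 without SGTA siRNA DHT replicate 1, 2 without SGTA siRNA DHT replicate 2, and 9 without control siRNA vehicle replicate 2 or SGTA siRNA vehicle replicate 3. CYP2U1 kept its call without each array, while LRRK1 (-0.79), STEAP1 (0.96), ACTRT3 (1.24) and MYNN (0.70) lost theirs without control siRNA DHT replicate 2. It was 3 with the replicate number as a block and 45 with array weights.

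Genes called by knockdown in vehicle and by DHT with control siRNA overlapped in 1286 genes, but these comparisons share the control siRNA vehicle arrays. They also share the fitted spread of each gene, so counts for independent calls are no chance values. Of the 1286 genes, 772 moved the same way and 514 opposite ways. There were 260 genes higher in both (165.7 if independent), 512 lower in both (270.3), 213 higher with knockdown and lower with DHT (172.4) and 301 lower with knockdown and higher with DHT (259.8). With the control arrays split between the comparisons, these means over 20 splits were 112.4 (74.31 if independent), 292.6 (145), 102 (80.06) and 167.6 (135.3), from fewer arrays. The covariance of the log2 changes was 0.0126, against 0.00374 simulated with no effects, the part that shared control arrays give. With the control arrays split it averaged 0.00822 and ran from -0.00119 to 0.0169 over 20 splits. In the simulation 0 genes were called in both. That follows from its lack of effects and gives no chance value for the overlap. The correlation was 0.15 and averaged 0.090 with split controls. The simulated correlation of 0.380 holds no real changes, so it is no reference for the observed one.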

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

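All tests of explanations in this part were chosen after the results were seen, except the test of list brightness and the counts over other splits of the vehicle arrays.

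Knockdown in vehicle raised G1/S genes and lowered hypoxia and glycolysis genes. The tables argue against a single array: both lists kept their call and direction in 20 of 20 settings without 1 vehicle array. They argue against list brightness too, since the G1/S median lay at percentile 100 and the hypoxia and glycolysis median at percentile 0 of 10000 random lists matched on mean expression. The DHT arrays, which share no array with this comparison, gave the same directions (camera adjusted p = 2.42e-14 and 3.47e-15; adjusted p = 0.046 and 0.14 with an estimated correlation). This fits an effect of the SGTA siRNAs as a hypothesis, but 1 pool cannot part loss of SGTA from other targets of the siRNAs, and neither list was called in vehicle with an estimated correlation (adjusted p = 0.0741 and 0.167).

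Among 100 of the 126 splits of the 10 vehicle arrays, 1 split, the real one, called as many as 1949 genes, and the highest other count was 1. This argues against a random grouping of these 10 arrays. It does not test chance differences between cultures or days, since the replicates may be technical. For lists, 4 of 100 splits called as many as the real 15, and the highest other count was 17. The other splits called a median of 6 of 28 lists. The real number of lists was thus high among the splits, but 3 other splits reached it, so chance is not excluded for this number. Each of the other splits holds the siRNAs in unequal shares, so they carry part of the knockdown. The knockdown also widens the spread within their groups, which lowers the number of genes they can call.

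DHT and vehicle arrays differed in 8204 genes. A remaining difference in the distribution of values is argued against, since 8144 genes were called after quantile normalization again. A response to the hormone fits, with the androgen-induced median at percentile 100 of matched random lists. The androgen-repressed list was not called, with control siRNA means of 7.377 in vehicle and 7.34 in DHT. Of olfactory receptor genes 10.6% were called, against 44.55% of all genes, which decides nothing here. Separate preparation of the DHT arrays cannot be told apart from the treatment, since no array is known to link the treatments. Part of the 8204 genes may therefore be technical.

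The interferon-stimulated list was called higher with knockdown in DHT by camera at the preset correlation (adjusted p = 0.000933), with 0 of 38 members called and adjusted p = 0.67 with an estimated correlation. The pattern may rest on 1 array of either siRNA. The mean change of the list was -0.21 without SGTA siRNA DHT replicate 2, and it was also small without control siRNA DHT replicate 2. List means in DHT ran from 6.08 to 6.82 with control siRNA and from 6.25 to 7.53 with SGTA siRNA. An effect of the knockdown stays open, because the vehicle difference of -0.033 (SE 0.33) is smaller than its error and the tests in DHT differ.

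In groups of 5 arrays, 8 of 160 tests found an array far from the others of its group; chance gives about 1 in 20. The gap was 0.747 of the range for CD24 (control siRNA vehicle replicate 1, lowest) and 0.82 for MTND2P28 (the same array, highest). It was 0.783 for CYP1A2 (SGTA siRNA vehicle replicate 3, lowest), 0.851 for KLK3 (replicate 5, lowest), 0.793 for MAB21L3 (replicate 5, lowest), 0.744 for LMO4 (replicate 2, highest), 0.767 for SNORD115-32 (replicate 4, lowest) and 0.75 for the basal epithelium list (replicate 3, highest).

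The DHT response differed between siRNAs by test in CYP2U1 (-1.08), STEAP1 (1.05), ACTRT3 (1.24), MYNN (0.76), LRRK1 (-0.80), UGT2B28 (1.5) and ACTA2 (0.99). Of these 7, CYP2U1 kept its call under all alternatives run. List medians differed by -0.15 for androgen-induced, -0.10 for unfolded protein response, 0.48 for interferon-stimulated, -0.16 for amino acid and -0.08 for ribosome biogenesis genes, and none of these 5 was called with an estimated correlation. The mean difference of the interferon-stimulated list turned negative without SGTA siRNA DHT replicate 2.

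Some probe sets outside the gene results were also called, in a fit of all 33297 probe sets with adjustment over them. Knockdown in vehicle called 200 of 12083 unlisted probe sets and 101 of 1754 probe sets with several symbols. Both shares were smaller than the 10.58% of genes called in the main fit.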

How the results depend on the processing

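Alternatives added after the data were seen were the crossed pairing, the removal of a pair of vehicle arrays and the removal of small nucleolar RNA genes; the cause of a change was not tested unless the setting itself gives it. SGTA kept its call and direction under all alternatives run (-1.97 to -1.89 in vehicle and -2.36 to -2.13 in DHT without 1 array). Stricter calling gives fewer genes by construction: with a change of at least 1.5-fold 138, 101, 3282 and 3093 genes were called for knockdown in vehicle, knockdown in DHT, DHT with control and DHT with SGTA siRNA; with adjusted p under 0.01 knockdown called 906 in vehicle and 86 in DHT, and 2 DHT responses differed. Knockdown in DHT gave 133 genes from its own arrays alone, 452 with a trend and robust prior, 666 with array weights, 479 among brighter genes and 162 with every probe set as a feature; differing DHT responses gave 29, 45, 29 and 2 under the last 4. Every probe set as a feature gave 12636 and 11742 for DHT with control and SGTA siRNA, from more features.

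Without 1 array the counts ran from 1484 to 1887 for knockdown in vehicle, 60 to 339 in DHT, 6261 to 8312 for DHT with control siRNA, 6022 to 7941 with SGTA siRNA and 1 to 19 for differing responses; a lone array was assumed to vary like the other groups. Without SGTA siRNA vehicle replicates 1 and 3, knockdown in vehicle called 1236 genes; the component on which they lie apart also separates the siRNAs, so a lower count is partly built in. Without small nucleolar RNA genes DHT called 8099 and 7572 genes.

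Same-numbered vehicle arrays had deviations correlated at -0.15 to 0.14, and 2 of 5 control arrays matched best with their own number. These values show no clear pairing by replicate number, but they were not tested and do not exclude shared cultures or days. The replicate block gave 1504, 152, 7586, 7015 and 3 genes for the 5 comparisons. The DHT pair correlated at -0.28, and the crossed pairing called 225 genes.

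With an estimated correlation 1, 2, 1, 1 and 0 lists were called for knockdown in vehicle, knockdown in DHT, DHT with control siRNA, DHT with SGTA siRNA and the difference, against 15, 13, 6, 5 and 5. For knockdown in vehicle, the oxidative phosphorylation and PI3K lists also lost their calls with the replicate block, with quantile normalization again, among brighter genes and without SGTA siRNA vehicle replicates 1 and 3, which added the chaperone, proteasome and interferon lists. The FOXO list lost its call with quantile normalization again and among brighter genes, and the G2/M and oxidative phosphorylation lists with fry. Fry called 16 lists for each DHT comparison, and brighter genes 3 for DHT with SGTA siRNA. Without 1 array the list counts ran from 10 to 16, 8 to 13, 6 to 7, 4 to 6 and 5 to 8. The interferon list turned to -0.21 for knockdown in DHT and -0.17 for the difference without SGTA siRNA DHT replicate 2, and its highest values were 1.08 and 1.11 without SGTA siRNA DHT replicate 1.

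The androgen-induced mean response with control siRNA was 1.47 among brighter genes, 1.53 with the mean of probe sets, 1.40 as a median and 1.53 to 1.59 without 1 array. With SGTA siRNA it was 1.36, 1.08 as a median and 1.37 to 1.40. The difference ran from -0.21 to -0.14 without 1 array. The overlap of knockdown and DHT calls was 546 at adjusted p under 0.01 (345 in the same direction), 675 on average with split controls (405) and 933 to 1210 without 1 array (538 to 750). Of named genes called, 76 of 93 for knockdown in vehicle, 10 of 40 in DHT, 111 of 120 for DHT with control siRNA, 104 of 113 with SGTA siRNA and 1 of 7 for the difference kept their call under every alternative run. Signal over background was not analysed here.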

Other observations

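The gene sets, families and neighbours in this part, and the test of stress-response genes, were chosen after the results were seen.

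Stress-response genes moved apart with SGTA knockdown in vehicle. Of 19 genes of the ATF4 arm, which responds to amino acid shortage and protein stress, 12 rose and 1 fell: CHAC1 (0.71), ASNS (0.60), SLC7A11 (0.60), ATF4 (0.42), TRIB3 (0.41), ATF5 (0.39) and DDIT3 (0.34) were among the rises and VLDLR (-0.37) was the fall. Of 18 ER chaperones and folding genes, 1 rose and 2 fell: PDIA4 (0.15), HSPA5 (-0.16) and EDEM1 (-0.50). The mean change was 0.26 in the ATF4 arm and -0.05 in the chaperones. The difference between the set means was 0.31 higher with SGTA siRNA (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 arrays can give). In DHT the mean changes were 0.10 and -0.09, with 1 gene of each set called. Of the 19 and 18 genes, 16 and 17 also belong to the fixed lists, and the sets were picked after the changes of their members were seen. This p therefore describes the difference and does not test whether lowering SGTA engages the ATF4 arm apart from ER chaperones, which stays open.

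Metallothionein genes, which bind zinc and copper, included MT1F, which rose with knockdown in vehicle (0.62 ± 0.06) and in DHT (0.81), and MT1H, which rose in vehicle (0.25 ± 0.07). Of 8 measured, 2 rose with knockdown in each treatment, and 5 rose with DHT and control siRNA. Among 192 small nucleolar and Cajal body RNA genes, 71 rose and 39 fell with DHT and control siRNA, and 18 rose and none fell with knockdown in vehicle.

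ACTRT3 and MYNN, neighbouring genes in the annotation, fell together with knockdown in vehicle (-1.19 and -0.75) and with DHT (-2.00 and -1.59 with control siRNA, -0.76 and -0.83 with SGTA siRNA). The next measured genes, LRRC34 and LRRIQ4, changed by -0.08 and -0.07 with knockdown and did not pass, while LRRC31 rose (0.93) and GPR160 fell (-0.27). With DHT and control siRNA, SERPINI1 (-1.63), LRRC31 (-1.13), GOLIM4 (-1.02) and GPR160 (-0.51) also fell, while MECOM (-0.26), LRRC34 (-0.07), LRRIQ4 (-0.03), SAMD7 (0.01) and SEC62 (0.06) did not pass. Of all genes, 44.6% were called in that comparison.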
